A study of Mus musculus with 18 samples.

How the data were processed

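RNA sequencing of 18 mouse CD8+ T cell libraries was analysed: sorted tumour-infiltrating OT-I cells (Nr4a1RFP+ 2, Tim-3+ 2, Ly108+ Nr4a1 WT 3, Ly108+ Nr4a1 KO 3) and cultured cells (Nr4a1-OV 2, RV-GFP 2, Nr4a1 WT 2, Nr4a1 KO 2). Per the submitters' notes, the authors trimmed reads with Trim Galore, aligned them to mm10 with HISAT2 and used edgeR and DESeq2, with versions not given. The read counter and the gene annotation were not given in the sources used here. Libraries were made by BGI or with Smartseq2, and the labels do not say which.

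The in vitro table held integer read counts per gene and library, which the authors deposited after trimming and alignment. The RPKM values deposited by the authors were counts scaled by gene length and library size, and in the in vitro table their library scale differed from TMM effective library sizes by at most 0.0184%. The tumour tables held RPKM without counts. The log2 fold changes deposited by the authors came from their own group comparisons and were used only for comparison with the values obtained here. Each p-value and adjusted p value deposited by the authors came from the same comparisons and was likewise used only as a reference. Columns named for exhausted cells were assigned to the Tim-3+ libraries, because Nr4a1RFP+ and Tim-3+ cells are the sorted populations that the series describes. A further 2 columns of values matched no labelled library and were not analysed here. In the in vitro table, 19 gene symbols had been turned into dates.

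The cultured libraries held 16.8 and 16.8 (Nr4a1-OV), 16.9 and 16.9 (RV-GFP), 17 and 17.1 (Nr4a1 WT) and 16.9 and 17 (Nr4a1 KO) M counts. Replicates of a group differed by more than counting error, with a chi-square per degree of freedom of 2.63 to 3.29 in culture, 11.4 between the Nr4a1RFP+ libraries, 42.3 between the Tim-3+ libraries and 2.08 to 11.2 among the Ly108+ libraries. Replicate numbers were not treated as pairs in the main tests, and were a block in an alternative, as fixed beforehand. In culture that alternative was fitted to only the 4 libraries compared. Deviations of libraries from their group means correlated positively between libraries of the same number (r across genes 0.243 for Nr4a1RFP+ and Tim-3+, 0.273 for Nr4a1-OV and RV-GFP, 0.161 for the cultured Nr4a1 KO and WT, and 0.313, 0.193 and 0.0052 for the Ly108+ libraries). Ly108+ libraries of different numbers gave -0.328 to 0.281. With 2 libraries per group, r for different numbers is fixed as the negative of r for the same number. These values therefore do not decide whether the numbers mark pairs.

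The groups, the tests, the gene lists, the rule for naming genes and the checks with other tools, filters and subsets of libraries were fixed before the data were examined. Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, scaled by TMM and tested with quasi-likelihood F tests in a single model of the 8 cultured libraries. RPKM values were analysed with limma 3.58.1 (limma-trend on log2 of RPKM plus 1), keeping genes at 1 RPKM or more in at least as many libraries as the smaller group held. All p-values were two-sided and adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Each of 19 gene lists was tested with camera against the other genes at a preset correlation of 0.01, and again with an estimated correlation. Each was also tested with fry, which asks whether a list changed at all, without comparing it with the other genes. List members were also adjusted over the list alone. Fisher's exact test was used for overlaps of calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15, and positions are from GENCODE M21 on GRCm38.

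Named genes were Nr4a1, Nr4a2 and Nr4a3, then the 8 highest and 8 lowest fold changes past the threshold with a mean log2 CPM or a mean value of at least 1, libraries that did not overlap and a named symbol. Largest increases and decreases in the Results are ranked only among genes that met these conditions. Each list added up to 4 members past the threshold by smallest p, or up to 2 members if none passed. For the comparison of Nr4a1-OV with Nr4a1 KO, the 8 opposite genes with the largest smaller absolute fold change were named. Where a group held 0 counts, a floor of 3 counts per library was used and the fold given as a lower bound, and where it held 1 to 3 counts an exact 95% interval of the ratio of counts was given.

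Whole reads were recovered from the tumour RPKM values and gene lengths for the 88.78% and 95.61% of genes with a length. Of values under 200 reads, 97.8% to 98.9% were whole numbers within 0.05. These alternatives were added after the data had been seen: edgeR, DESeq2 1.42.0 and limma-voom on recovered reads, RPKM rescaled by median ratios, the interaction of genotype and setting on recovered reads, and the removal of genes within 20 Mb of Nr4a1. Of the checks fixed at the start, count-based tools on deposited tumour counts and an interaction on deposited counts were not run, because the tumour tables hold RPKM. A pseudocount change was not run for the cultured cells, whose counts were tested directly.

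The pipeline was tested on simulated data with 200 changed genes per comparison. Genes changed by log2 1 were recovered at 89.7% (Nr4a1RFP+ against Tim-3+), 82.5% (Nr4a1-OV), 87.4% (cultured Nr4a1 KO) and 92.8% (Ly108+), with 18, 13, 9 and 5 false calls. These percentages cover only the changed genes that passed the filter (78, 97, 95 and 83). Far more genes passed in the real Nr4a1-OV comparison (60.9% of those tested), so the simulation does not test scaling in that setting. The simulated interaction gave 79% recovery and 6 false calls. Fold changes were checked against the authors' columns, with r across genes of 0.928, 0.998, 0.999 and 0.969.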

Results

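Messenger RNA was measured by RNA sequencing in 18 libraries of mouse CD8+ T cells that fall into 8 groups. Tumour-infiltrating OT-I cells, which carry a transgenic T cell receptor for an ovalbumin peptide, were sorted as Nr4a1RFP+ (2 libraries) or Tim-3+ (2 libraries) on day 21 after tumour inoculation, and as Ly108+ cells labelled Nr4a1 WT (3 libraries) or Nr4a1 KO (3 libraries). Cultured CD8+ T cells were infected with a retrovirus for Nr4a1 (Nr4a1-OV, 2 libraries) or with the control virus RV-GFP (2 libraries), or were activated with antibodies to CD3 and CD28 and labelled Nr4a1 WT (2 libraries) or Nr4a1 KO (2 libraries). All 8 cultured libraries were from cells restimulated for 2 h with PMA and ionomycin, which bypass the T cell receptor. NR4A1 (Nur77) is a nuclear receptor transcription factor whose gene is switched on within hours of T cell receptor signalling. The cultured libraries held 16.8 to 17.1 M counts each over 17738 genes. The reads recovered from the normalised values of the tumour libraries came to 22.1 and 23.5 M for Nr4a1RFP+ cells, 17.7 and 24.1 M for Tim-3+ cells, 15.2, 15.4 and 15.5 M for Ly108+ Nr4a1 WT cells and 15.7, 15.8 and 15.8 M for Ly108+ Nr4a1 KO cells. The labels do not say whether replicates came from separate animals or cultures, so each p-value measures only the spread between these libraries.

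Nr4a1 itself (chromosome 15, 101254269 to 101274795, GRCm38) was read in every library. In Nr4a1-OV cells it averaged 5196 ± 164 CPM (read counts scaled by library size; SD, n = 2) against 2087 ± 149 in RV-GFP cells, a log2 fold change of 1.32 (SE 0.06, adjusted p = 2.08e-13). Both Nr4a1RFP+ libraries lay below both Tim-3+ libraries, at 114 ± 0.995 and 129 ± 4.88 RPKM (n = 2 each, log2 fold change -0.17), but the difference did not pass the threshold (adjusted p = 0.364). The libraries labelled Nr4a1 KO did not hold less Nr4a1 than those labelled Nr4a1 WT. In culture, the KO libraries held 361.4 and 360.2 CPM and the WT libraries 290.3 and 338.1 CPM, a log2 fold change of 0.20 (adjusted p = 0.0171). That call ended without Nr4a1 WT replicate 1 (log2 fold change 0.10, adjusted p = 0.279), without Nr4a1 KO replicate 1 (adjusted p = 0.0685) and without Nr4a1 KO replicate 2 (adjusted p = 0.0666), and the log2 fold change was 0.31 without Nr4a1 WT replicate 2. In Ly108+ cells, the KO libraries held 112.4, 100.6 and 102.2 RPKM and the WT libraries 53.89, 46.37 and 45.02 RPKM, a log2 fold change of 1.10 (SE 0.08, adjusted p = 0.000434). Values per gene cannot show whether a deleted part of the gene was missing from these transcripts, so the groups are named by their labels throughout. Whether the cells labelled Nr4a1 KO and Nr4a1 WT had the same genetic background is not given in the sources used here, so differences between them need not follow from Nr4a1. Of its paralogs, Nr4a2 fell in Nr4a1-OV cells (log2 fold change -0.58) and rose in the cultured KO libraries (0.48), where Nr4a3 rose too (0.59). Nr4a3 also passed the threshold in Nr4a1RFP+ cells (0.53) and, as a decrease, in Nr4a1-OV cells (-0.18). The former call ended without Nr4a1RFP+ replicate 1 (adjusted p = 0.227) or replicate 2 (adjusted p = 0.115), and the latter without Nr4a1-OV replicate 2 (adjusted p = 0.112). Neither paralog passed the threshold between the Ly108+ groups (adjusted p = 0.495 for Nr4a2 and 0.703 for Nr4a3).

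**Figure D1:**
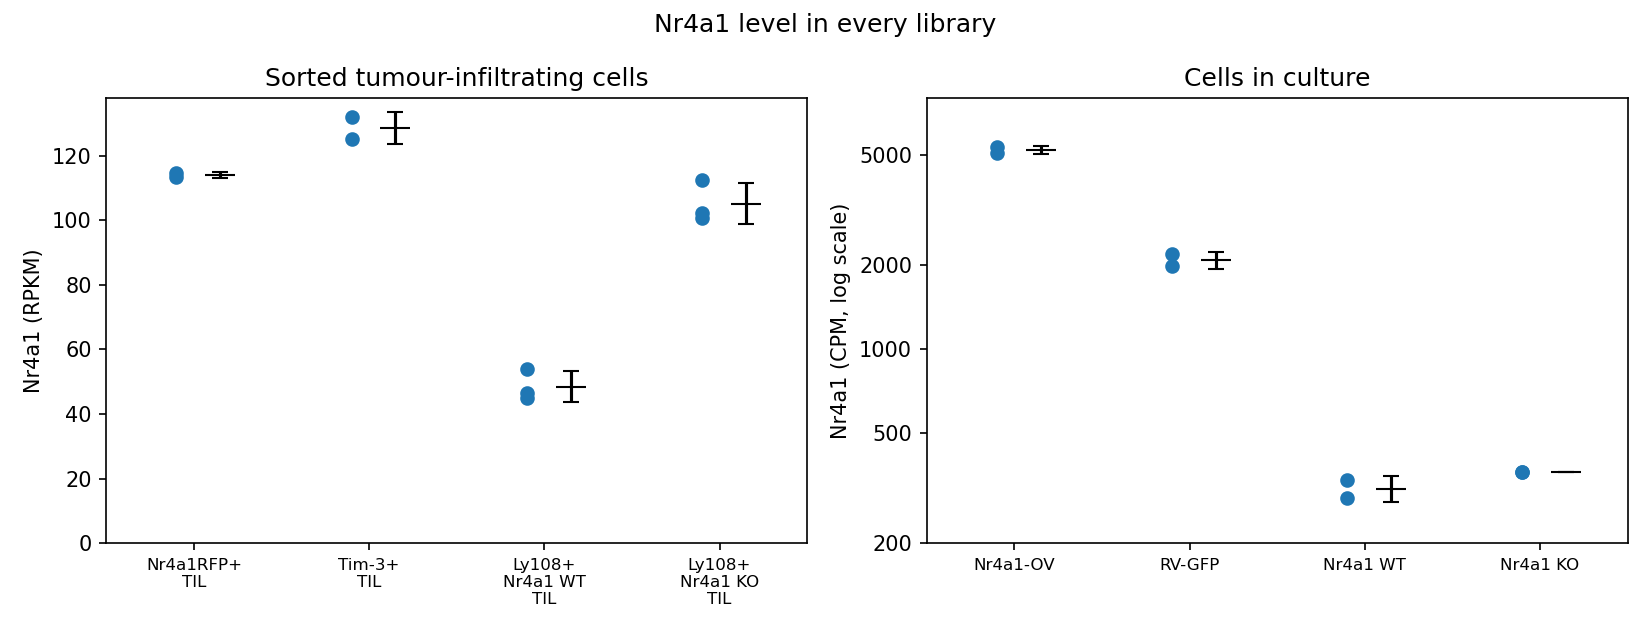
Nr4a1 level in each library (points) with the group mean and SD beside them, in RPKM for tumour-infiltrating cells (left) and in CPM on a log axis for cultured cells (right). Both Nr4a1-OV libraries (5081 and 5312 CPM) lie above both RV-GFP libraries (1982 and 2192 CPM), and all 3 Ly108+ Nr4a1 KO libraries (100.6 to 112.4 RPKM) lie above all 3 Ly108+ Nr4a1 WT libraries (45.02 to 53.89 RPKM).

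The comparison of Nr4a1RFP+ with Tim-3+ cells asks how tumour-infiltrating T cells sorted for the Nr4a1 reporter differ from those that carry Tim-3, an inhibitory receptor of dysfunctional T cells encoded by Havcr2. Many genes of naive, memory and stem-like T cells rose in Nr4a1RFP+ cells and many of cytotoxic effectors fell, though neither list passed with an estimated correlation (adjusted p = 0.313 each). Tcf7, which encodes the transcription factor TCF-1 of stem-like T cells, averaged 103 ± 1.38 RPKM in Nr4a1RFP+ and 4.07 ± 1.95 in Tim-3+ cells (SD, n = 2 each, log2 fold change 4.42). Ccr7, a lymph node homing receptor, averaged 3907 ± 268 against 292 ± 56.7 RPKM. Gzmb, which encodes granzyme B, fell from 1821 ± 132 RPKM in Tim-3+ cells to 126 ± 42.4 in Nr4a1RFP+ cells (log2 fold change -3.88), and Havcr2 from 225 ± 14.8 to 15.7 ± 3.81 RPKM (-3.78), as the sort would require. Of 9508 genes tested, 1682 passed the threshold, 863 higher and 819 lower in Nr4a1RFP+ cells, and 273 and 220 of these by at least 2-fold in RPKM plus 1.

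Beyond Tcf7 and Ccr7, the largest increases in Nr4a1RFP+ cells were those of Dapl1 (log2 fold change 5.65, SE 0.16), Ccr6, a chemokine receptor (4.90, SE 0.16), Igfbp2, an insulin-like growth factor binding protein (4.25, SE 0.24), the activation marker Cd83 (4.22, SE 0.13), Lad1 (3.53, SE 0.15) and the nuclease gene Dnase1l3 (3.52, SE 0.15). The largest decreases included Gzma (-4.04, SE 0.41), the chemokine Ccl5 (-4.04, SE 0.43), Gzmf (-3.85, SE 0.16), the adhesion receptor Adgrg1 (-3.27, SE 0.11), the metalloproteinase Adam8 (-3.12, SE 0.17) and Gzmc (-3.09, SE 0.21). Tcf7 lies on chromosome 11 at 52252371 to 52283014, Havcr2 on chromosome 11 at 46454935 to 46481255 and Gzmb on chromosome 14 at 56258838 to 56262260.

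Of 18 stem-like and naive-memory genes, 12 rose and 0 fell in Nr4a1RFP+ cells, and 14 passed adjusted over the list alone. They included Tnfsf8 (log2 fold change 3.09), the follicular homing receptor Cxcr5 (2.96) and Slamf6 (2.68), which encodes Ly108. The list was higher than the other genes by camera (adjusted p = 9.28e-12, and adjusted p = 0.313 with an estimated correlation). Of 21 cytotoxic effector genes, 16 fell and 0 rose (17 adjusted over the list alone), among them Gzmd (-2.70) and Prdm1 (-2.53), which encodes Blimp-1 (adjusted p = 2.94e-13, and 0.313 with an estimated correlation). Of 15 type I interferon response genes, 10 fell and 0 rose (11 adjusted over the list alone), including Isg15 (-1.56), Isg20 (-1.20) and Ifit3 (-1.11), with an adjusted p = 1.03e-06, and an adjusted p = 0.548 with an estimated correlation. Of 26 cell cycle genes, 7 fell and 0 rose (15 adjusted over the list alone), with Birc5, which encodes survivin, at -1.36 (adjusted p = 1.96e-06, adjusted p = 0.603 with an estimated correlation and 0.265 with fry).

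Other groups split. Of 15 inhibitory receptor and exhaustion genes, 4 rose and 5 fell (12 adjusted over the list alone, adjusted p = 0.256): besides Havcr2, Cd244a (log2 fold change -2.97) and Entpd1 (-2.94) fell, and Nt5e rose (2.08). Of 18 cytokine and chemokine ligand genes, 6 rose and 7 fell (15 adjusted over the list alone). Tnfsf11, which encodes RANKL (2.98), and Csf2, which encodes GM-CSF (2.27), rose and Ccl3 fell (-2.97), while Il3 rose from a group in which it is listed at 0. The list's median log2 fold change was 0.20, its mean -0.05 and its camera direction higher, with an adjusted p = 0.747. Of 24 activation-induced transcription factor genes, 6 rose and 6 fell (15 adjusted over the list alone, adjusted p = 0.959), with Egr1, an immediate early gene, at -1.76 and Atf3 at -0.98. Of 15 chemokine receptor, homing and residency genes, 2 rose and 5 fell (9 adjusted over the list alone, adjusted p = 0.268), with Ccr2 at -3.02, Cxcr6 at -2.40 and Ccr6 rising as given above. Of 24 T cell receptor signalling and costimulation genes, 1 rose (Tnfrsf4, which encodes OX40, 1.11) and 1 fell (Cd226, -0.74), with 2 adjusted over the list alone and an adjusted p = 0.161. The call of Cd226 ended without Nr4a1RFP+ replicate 1 (adjusted p = 0.051) or replicate 2 (adjusted p = 0.0555).

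Of 18 apoptosis genes, 3 rose and 1 fell (6 adjusted over the list alone, adjusted p = 0.548), with the death receptor gene Fas at 1.49 and the survival gene Bcl2 at 0.89. Of 17 glycolysis genes, 2 rose and 1 fell (3 adjusted over the list alone), the latter being the glucose transporter gene Slc2a3 (-1.17). The median of that list was 0.01 and its mean -0.03 (adjusted p = 0.795). None of 17 oxidative phosphorylation genes passed (0 adjusted over the list alone, adjusted p = 0.548; Cox5a at an adjusted p = 0.0518 and Sdha at 0.161). Cox5a was called lower with replicate numbers as a block (0.0142) and with each count-based tool on recovered reads (0.0109 to 0.0487). Its log2 fold change was -0.346 without Tim-3+ replicate 1 and -0.768 without Tim-3+ replicate 2. Sdha went the other way, with a log2 fold change of 0.51 without Tim-3+ replicate 2. Of 10 heat shock and dissociation stress genes, 2 fell and 0 rose (3 adjusted over the list alone, adjusted p = 0.643), one of them Hspa1b (-0.83).

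Markers of other cell types moved in both directions between the sorted groups. Of 5 myeloid markers, 1 rose (Cd68, log2 fold change 1.52) and 2 fell, including Tyrobp (-1.03), with 3 adjusted over the list alone and an adjusted p = 0.997. Of 3 tumour and stromal markers, Pecam1 (0.85) and Pmel (0.70) rose (3 adjusted over the list alone, adjusted p = 0.0191, and 0.548 with an estimated correlation). Pmel did not pass without Nr4a1RFP+ replicate 1 (adjusted p = 0.0535), nor the list without Tim-3+ replicate 2 (adjusted p = 0.0829) or on recovered reads (0.209). The 1 B cell marker tested, Cd79b, rose (0.49, 1 adjusted over the list alone, adjusted p = 0.256 for the list), but not without Nr4a1RFP+ replicate 2 (adjusted p = 0.195) or with any count-based tool on recovered reads (0.0811 to 0.218). Of 2 CD4 and regulatory T cell markers, Ikzf2, which encodes the transcription factor Helios, rose (1.83, 1 adjusted over the list alone, adjusted p = 0.256), and of 2 NK and innate lymphocyte markers Fcer1g fell (-2.82, 1 adjusted over the list alone, adjusted p = 0.191). None of 4 erythroid markers passed (0 adjusted over the list alone, adjusted p = 0.71): Hba-a1 averaged 10.5 ± 13.9 RPKM in Nr4a1RFP+ and 8.60 ± 2.20 in Tim-3+ cells.

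All libraries of one group lay above all of the other for 61.2% of the genes tested, against 33.3% by chance. The count of 1682 depended on the library left out: 924 without Nr4a1RFP+ replicate 1, 763 without Nr4a1RFP+ replicate 2, 2989 without Tim-3+ replicate 1 and 3359 without Tim-3+ replicate 2. Each of these left 1 library in a group, so the spread then came from the other group alone. The authors' deposited comparison called 2273 genes, of which 1558 were called here with the same sign.

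Infection with the Nr4a1 retrovirus asks which transcripts change when CD8+ T cells are given more Nr4a1. Of 19 cytokine and chemokine ligand genes, 18 fell in Nr4a1-OV cells, though the list did not pass with an estimated correlation (adjusted p = 0.063). Il2, which encodes the T cell growth factor interleukin 2, fell from 254 ± 9.39 to 23.6 ± 1.5 CPM (SD, n = 2 each, log2 fold change -3.43, adjusted p = 3.03e-19), and Tnf from 635 ± 33.9 to 166 ± 7.08 CPM (-1.93). Foxp3, the lineage transcription factor of regulatory T cells, rose from 3.20 ± 0.448 to 256 ± 1.18 CPM (6.32, SE 0.11), and Ccr7 from 171 ± 10.1 to 1448 ± 91.3 CPM (3.08, SE 0.06). All 26 cell cycle genes tested fell. Of 14994 genes, 9125 passed the threshold, 4688 higher and 4437 lower in Nr4a1-OV cells, and of these 1875 rose and 512 fell by at least 2-fold. Decreases were the more numerous with RLE scaling (4403 higher and 4800 lower), DESeq2 (3653 and 4074) and at least 1 CPM in every library of a group (4291 and 4750). The median log2 fold change of all genes, 0.0187, turned to -0.00926 without RV-GFP replicate 1 and -0.00879 without RV-GFP replicate 2.

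Csf2rb and Csf2rb2, which encode the common beta receptor chain for GM-CSF and interleukin 3 and its paralog, were close to absent from the control. Csf2rb averaged 109 ± 0.106 CPM in Nr4a1-OV cells, 1110 times the RV-GFP level (95% interval 381 to 5400), and Csf2rb2 19.6 ± 0.533 CPM, 601 times that level (107 to 23800). The corresponding ratio of Nos1ap was 381 (68.1 to 15100). The mast cell carboxypeptidase gene Cpa3, the cell adhesion gene Nrcam, Pdk4, which encodes an inhibitor of pyruvate dehydrogenase, Neto1 and Lcn10 had 0 counts in both RV-GFP libraries. Against a floor of 3 counts per library they were at least 58.2-fold, 54.3-fold, 47.9-fold, 26.6-fold and 20.9-fold higher in Nr4a1-OV cells. Besides Il2, the largest decreases were those of Il10 (log2 fold change -3.89, SE 0.28), Siglecf (-2.88, SE 0.15), the decoy receptor gene Il1r2 (-2.83, SE 0.17), Ccr2 (-2.80, SE 0.19), Il3 (-2.79, SE 0.12), Il23a (-2.76, SE 0.29) and Cd40lg (-2.75, SE 0.10). Foxp3 lies on the X chromosome at 7573644 to 7595245, Il2 on chromosome 3 at 37120523 to 37125959 and Csf2rb on chromosome 15 at 78325752 to 78353847. Intervals and floors cover counting error only.

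The cytokine and chemokine ligand genes that fell included Ccl4 (log2 fold change -1.69) and Tnfsf14 (-1.52) besides Il2 and Tnf, and 1 gene rose (19 adjusted over the list alone). The list was lower than the other genes by camera (adjusted p = 1.64e-29, and adjusted p = 0.063 with an estimated correlation). The 26 cell cycle genes (26 adjusted over the list alone) gave an adjusted p = 2.19e-10, and an adjusted p = 0.317 with an estimated correlation. The DNA replication licensing genes Mcm3 (-1.06), Mcm2 (-0.98), Mcm5 (-0.95) and Mcm4 (-0.85) had the smallest p-values. Of 19 stem-like and naive-memory genes, 12 rose and 5 fell (17 adjusted over the list alone, adjusted p = 1.78e-05, and 0.382 with an estimated correlation). Ccr7, the transcription factor gene Myb (2.28) and the interleukin 7 receptor gene Il7r (1.80) rose, and Slamf6 fell from 270 ± 3.02 to 95.3 ± 2.36 CPM. Of 15 inhibitory receptor and exhaustion genes, 10 rose and 4 fell (14 adjusted over the list alone, adjusted p = 0.0021, and 0.101 with an estimated correlation). Cd101 (4.19), Tox, which encodes a transcription factor of exhausted T cells (1.63), Nt5e (1.47) and the checkpoint receptor gene Ctla4 (1.35) rose.

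Of 5 CD4 and regulatory T cell markers, Foxp3, Ikzf2 (log2 fold change 3.10) and Zbtb7b (1.05) rose and Cd40lg fell (4 adjusted over the list alone, adjusted p = 3.51e-06, and 0.063 with an estimated correlation). Of 17 oxidative phosphorylation genes, 12 fell and 1 rose (13 adjusted over the list alone, adjusted p = 0.0396, and 0.568 with an estimated correlation), with Cycs, which encodes cytochrome c, at -0.66 and Atp5b at -0.57. That list did not pass without Nr4a1-OV replicate 1 (adjusted p = 0.0608). Of 9 heat shock and dissociation stress genes, 5 fell and 0 rose (5 adjusted over the list alone, adjusted p = 0.019, and 0.33 with an estimated correlation), among them the chaperone genes Hspe1 (-0.98) and Hsp90ab1 (-0.70). The 1 NK and innate lymphocyte marker tested, the interleukin 33 receptor gene Il1rl1, fell (-2.49, 1 adjusted over the list alone, adjusted p = 0.000703, and 0.101 with an estimated correlation).

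Many genes of the remaining lists passed, in both directions. Of 18 cytotoxic effector genes, 6 rose and 7 fell (13 adjusted over the list alone, adjusted p = 0.939): Tnfsf10, which encodes the death ligand TRAIL (log2 fold change 3.27), and Ccl5 (1.34) rose, and Nkg7 (-1.47) and Gzmb (-1.01) fell. Of 26 activation-induced transcription factor genes, 7 rose and 13 fell (20 adjusted over the list alone, adjusted p = 0.266), with Jun at 1.08 and Egr1 at -0.95. Of 24 T cell receptor signalling and costimulation genes, 11 rose and 7 fell (19 adjusted over the list alone, adjusted p = 0.258), with Plcg1 at 1.15 and Lcp2 at -0.60. Of 18 chemokine receptor, homing and residency genes, 9 rose and 7 fell (16 adjusted over the list alone), with the integrin gene Itga4 at 1.56 and Itgb1 at -0.91. The median of that list was 0.15 and its mean 0.19, though camera gave its direction as lower (adjusted p = 0.982). Of 17 glycolysis genes, 3 rose and 11 fell (14 adjusted over the list alone, adjusted p = 0.183), with the hexokinase genes Hk1 at 0.68 and Hk2 at -0.80. Of 21 type I interferon response genes, 9 rose and 6 fell (15 adjusted over the list alone), with Ifit2 at 1.29. Their median was -0.02, their mean 0.00 and the camera direction higher (adjusted p = 0.472).

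Of 19 apoptosis genes, 11 rose and 6 fell (17 adjusted over the list alone, adjusted p = 0.258): Pmaip1, which encodes the pro-apoptotic protein Noxa (log2 fold change 1.30), Apaf1 (1.16) and Fas (1.13) rose. Of 3 myeloid markers, Cd68 (-0.67) and Apoe (-0.64) fell (2 adjusted over the list alone, adjusted p = 0.521). All 5 B cell markers tested rose (5 adjusted over the list alone, adjusted p = 0.258), including Ebf1 (1.83) and Ighm (0.33). The calls of the other named members ended in some settings. Cd79b (0.94) did not pass without Nr4a1-OV replicate 1 (adjusted p = 0.0772) or RV-GFP replicate 2 (adjusted p = 0.0756). Fcmr (1.02 CPM in Nr4a1-OV and 0.359 in RV-GFP) did not pass without Nr4a1-OV replicate 2 (adjusted p = 0.0614) or RV-GFP replicate 2 (adjusted p = 0.0535), nor with DESeq2 (0.0846). Of 5 tumour and stromal markers, Pmel (1.85) and Pecam1 (0.55) rose and 0 fell (4 adjusted over the list alone, adjusted p = 0.266). No erythroid marker was high enough to test. The libraries of the groups did not overlap for 79.6% of genes, against 33.3% by chance, and the authors called 7642 genes, 7577 of them called here with the same sign.

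Cultured cells labelled Nr4a1 KO and Nr4a1 WT were compared to ask what differs between these labels. The libraries labelled Nr4a1 KO held more RNA for cytotoxic molecules and interferon response genes. Of 19 cytokine and chemokine ligand genes 14 rose, but that list did not pass with an estimated correlation (adjusted p = 0.157). Gzmb rose from 3370 ± 337 to 13970 ± 836 CPM (SD, n = 2 each, log2 fold change 2.05, adjusted p = 5.38e-16), Prf1, which encodes the pore-forming protein perforin, from 240 ± 8.81 to 1084 ± 24.3 CPM (2.17) and Ifng from 386 ± 109 to 2010 ± 83.6 CPM (2.38). Havcr2 rose from 4.02 ± 1.40 to 32.0 ± 2.31 CPM (2.99), while Tox fell from 73.3 ± 3.36 to 23.6 ± 1.54 CPM (-1.63) and Id3, a transcriptional regulator of memory T cells, from 48.2 ± 6.23 to 11.3 ± 0.755 CPM (-2.09). Of 14994 genes, 6007 passed the threshold, 2762 higher and 3245 lower in the libraries labelled Nr4a1 KO, and of these 682 rose and 316 fell by at least 2-fold. Which direction held more genes depended on the settings, with 3219 higher and 2638 lower with upper-quartile factors and 3000 and 2878 with at least 1 CPM in every library of a group. With only the 4 libraries compared it was 2943 and 2827, and 2987 and 2884 with replicate numbers as a block in those 4.

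The largest increases included the interferon-induced genes Oasl2 (log2 fold change 5.18, SE 0.20) and Ifi44 (4.29, SE 0.18), the inflammatory chemokine receptor gene Ccr2 (4.43, SE 0.17), Serpinb9b (4.36, SE 0.12), Gzmc (4.14, SE 0.11) and Bst1 (4.06, SE 0.18). The orphan receptor gene Gpr141 was 55.6 times as high in the libraries labelled Nr4a1 KO (95% interval 15 to 465). Esm1 also passed, with 0 counts in the Nr4a1 WT libraries. Its mean in the libraries labelled Nr4a1 KO (0.145 CPM) lay below the floor of 3 counts per library (0.166 CPM), so no fold is given. Its call ended without Nr4a1 WT replicate 1 (adjusted p = 0.122), without Nr4a1 WT replicate 2 (adjusted p = 0.128) and without Nr4a1 KO replicate 1 (adjusted p = 0.259), and with DESeq2 (0.0567). Slc15a2, a peptide transporter gene, had 0 counts in both libraries labelled Nr4a1 KO and was at least 10.1-fold lower there. Ankrd33b and Cpa3 were lower by ratios of 14.8 (95% interval 4.74 to 74.2) and 13 (3.26 to 113). Zan (-3.55, SE 0.24), Fam81a (-3.49, SE 0.28), Otx1 (-3.38, SE 0.31), Foxp3 (-3.36, SE 0.21) and the cation channel gene Trpm1 (-3.23, SE 0.14) completed the largest decreases among genes that met the naming rule. Prf1 lies on chromosome 10 at 61297833 to 61304680, Ifng on chromosome 10 at 118441046 to 118445892 and Oasl2 on chromosome 5 at 114896936 to 114912234.

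Of 18 cytotoxic effector genes, 16 rose and 1 fell (17 adjusted over the list alone, adjusted p = 3.33e-35), including the death ligand gene Fasl (log2 fold change 1.71). Of 21 type I interferon response genes, 18 rose and 0 fell (18 adjusted over the list alone, adjusted p = 1.99e-24), including Usp18 (1.90) and Isg20 (1.84). Both calls held with an estimated correlation (adjusted p = 0.0141 for each). Of 19 cytokine and chemokine ligand genes, 14 rose and 3 fell (18 adjusted over the list alone, adjusted p = 4.81e-10, and 0.157 with an estimated correlation), with Ccl4 at 1.29, Spp1 at 1.17 and Csf1 at -1.70. Of 26 activation-induced transcription factor genes, 16 rose and 4 fell (20 adjusted over the list alone, adjusted p = 2.5e-06, and 0.279 with an estimated correlation), with Ier3 at 2.32, Dusp5 at 1.09, Jun at 0.99 and Fosl2 at 0.99. Of 26 cell cycle genes, 21 fell and 0 rose (22 adjusted over the list alone, adjusted p = 5.86e-09, and 0.279 with an estimated correlation), including Cdc20 (-0.84), Plk1 (-0.68) and Birc5 (-0.67). Of 19 stem-like and naive-memory genes, 4 rose and 11 fell (16 adjusted over the list alone, adjusted p = 0.00951, and 0.503 with an estimated correlation). Besides Id3, Slamf6 (-1.10) and Lef1 (-0.86) fell, whereas Il7r rose (1.44). That list did not pass without Nr4a1 WT replicate 2 (adjusted p = 0.0766).

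Of 15 inhibitory receptor and exhaustion genes, 5 rose and 7 fell (13 adjusted over the list alone). Btla (log2 fold change -0.85) and Nt5e (-0.66) fell with Tox, and Havcr2 rose. The median of that list was -0.18, its mean 0.10 and its camera direction lower (adjusted p = 0.47). Of 18 chemokine receptor, homing and residency genes, 6 rose and 7 fell (15 adjusted over the list alone, adjusted p = 0.075), with S1pr4 at -0.91. Of 24 T cell receptor signalling and costimulation genes, 6 rose and 11 fell (18 adjusted over the list alone, adjusted p = 0.236): Tnfrsf9, which encodes 4-1BB, rose (0.73) and the inhibitory coreceptor gene Cd5 fell (-0.78). Of 17 glycolysis genes, 6 rose and 6 fell (12 adjusted over the list alone, adjusted p = 0.3), with Slc2a3 at 1.63 and Tpi1 at -0.60. Of 17 oxidative phosphorylation genes, 2 rose and 7 fell (10 adjusted over the list alone, adjusted p = 0.236), with Ndufv1 at -0.34. Of 19 apoptosis genes, 8 rose and 6 fell (15 adjusted over the list alone, adjusted p = 0.482), the latter including the pro-apoptotic genes Bmf (-1.51), Bcl2l11, which encodes Bim (-1.17), and Bbc3, which encodes Puma (-0.66). Of 9 heat shock and dissociation stress genes, 5 rose and 1 fell (7 adjusted over the list alone, adjusted p = 0.3), with Hsp90aa1 at 0.28 and Dnajb1 at -0.32.

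Among markers of other cells in the cultured libraries labelled Nr4a1 KO, Cd68 rose (log2 fold change 1.49) and Apoe fell (-0.40) of 3 myeloid markers (2 adjusted over the list alone). The call of Apoe ended without Nr4a1 WT replicate 1 (adjusted p = 0.0946), Nr4a1 WT replicate 2 (adjusted p = 0.0807) or Nr4a1 KO replicate 2 (adjusted p = 0.185), with replicate numbers as a block (0.0528), with DESeq2 (0.127) and with upper-quartile factors (0.0548). The median of that list was -0.26, its mean 0.28 and its camera direction higher (adjusted p = 0.322). Of 5 B cell markers, Ebf1 rose (1.95) and Ighm fell (-0.93; 2 adjusted over the list alone), and the list had a median of 0.37 and a mean of 0.28 but a camera direction of lower (adjusted p = 0.523). Of 5 CD4 and regulatory T cell markers, 1 rose and 3 fell (4 adjusted over the list alone, adjusted p = 0.0842), with Foxp3 and Cd40lg (-1.23) falling and Zbtb7b rising (0.83). Il1rl1, the 1 NK and innate lymphocyte marker tested, rose (0.58, 1 adjusted over the list alone, adjusted p = 0.3). Of 5 tumour and stromal markers, Epcam rose (0.62) and Pmel (-0.94) and Pecam1 (-0.70) fell (3 adjusted over the list alone, adjusted p = 0.322). Erythroid markers were too low to test. The groups did not overlap for 69% of genes, against 33.3% by chance, and the authors called 4282 genes, 4280 of them called here with the same sign.

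The comparisons of Nr4a1-OV with RV-GFP and of cultured Nr4a1 KO with Nr4a1 WT were then set side by side to ask whether the same genes went opposite ways. Of 4270 genes past the threshold in both comparisons, 2592 (60.7%) had opposite signs. Among these were 1372 genes higher in Nr4a1-OV and lower in the libraries labelled Nr4a1 KO, against 1015 for independent calls (odds ratio 1.86, Fisher's exact test, two-sided p = 7.24e-51), and 1220 with the reverse signs, against 817 (odds ratio 2.22, p = 5.65e-73). By the same exact test, fewer genes than for independent calls were higher in both (793 against 864, odds ratio 0.862, p = 0.00135) or lower in both (885 against 960, odds ratio 0.865, p = 0.00104). Across all 14994 genes, the fold changes had a Pearson r of -0.12 and a Spearman rho of -0.143. Leaving out 1 cultured library gave a Pearson r from -0.153 (Nr4a1 KO replicate 2) to -0.0535 (Nr4a1 WT replicate 2). Genes are not independent replicates, so the exact tests and the correlations describe the overlap only. The genes that moved farthest in opposite directions were Foxp3, Trpm1 (log2 fold change 6.59, SE 0.20, in Nr4a1-OV), Cpa3, Ankrd33b (3.92, SE 0.20, in Nr4a1-OV), the integrin gene Itga9 (3.33 in Nr4a1-OV and -3.50 in the libraries labelled Nr4a1 KO), the protease gene Adamts20 and the vasopressin receptor gene Avpr1a, all higher in Nr4a1-OV cells, and Pilrb1, lower there. Adamts20, Avpr1a and Pilrb1 were close to 0 counts in one group, so their folds are not given.

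Counts of opposite signs were also taken within each list, without a test between lists. Of 17 cytokine and chemokine ligand genes past the threshold in both comparisons, 15 had opposite signs, 14 of them lower in Nr4a1-OV and higher in the libraries labelled Nr4a1 KO. Of 12 apoptosis genes, 10 were opposite, and of 12 inhibitory receptor and exhaustion genes, 8. Tox and Nt5e, for example, were higher in Nr4a1-OV cells and lower in the libraries labelled Nr4a1 KO. Of 12 cytotoxic effector genes, 7 were opposite, as were 7 of 14 stem-like and naive-memory genes and 6 of 12 type I interferon response genes. None of 21 cell cycle genes was opposite: all 21 were lower in both.

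**Figure D2:**
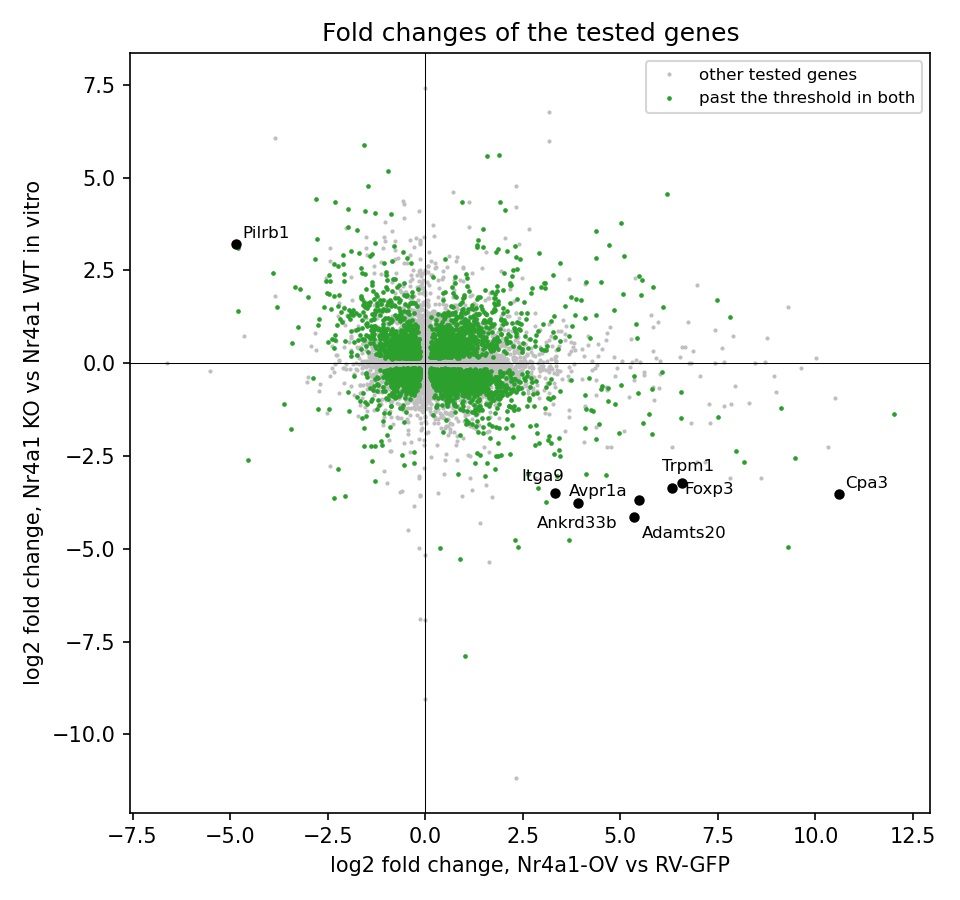
Log2 fold change of each tested gene for Nr4a1-OV against RV-GFP (horizontal axis) and for cultured Nr4a1 KO against Nr4a1 WT (vertical axis), with genes past the threshold in both in green, others in grey and the 8 genes that moved farthest in opposite directions in black with names. Of the 4270 green and black points, 2592 lie in the upper left and lower right quadrants, among them Foxp3 at 6.32 and -3.36.

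Ly108+ cells labelled Nr4a1 KO and Nr4a1 WT were compared to ask what differs between these labels in the stem-like cells of the tumour, which Ly108 marks. Fewer genes passed than in the other comparisons, and the lists of stem-like, exhausted and cytotoxic T cell genes did not pass. Nr4a1 KO replicate 1 stood apart from replicates 2 and 3 (chi-square per degree of freedom 9 and 11.2, against 2.69 between those). Nr4a1 WT replicate 1 did so less (5.1 and 5.35, against 2.08). The number of genes called varied with the library left out, as given below. The largest decreases were those of the protease gene Ctse, which fell from 53.3 ± 2.60 to 4.58 ± 0.525 RPKM (SD, n = 3 each, log2 fold change -3.29, adjusted p = 8e-07), Osr2 (16.2 ± 1.10 to 1.27 ± 0.277 RPKM, -2.92) and the antiviral deaminase gene Apobec3 (13.5 ± 0.175 to 2.44 ± 0.368 RPKM, -2.08). Dennd3 rose from 3.18 ± 0.330 to 12.7 ± 0.894 RPKM (1.72, adjusted p = 3.89e-05) and Spp1, which encodes osteopontin, from 7.90 ± 1.12 to 17.1 ± 2.15 RPKM (1.02, adjusted p = 0.00566). Of 11265 genes, 501 passed the threshold, 230 higher and 271 lower in the libraries labelled Nr4a1 KO. Of these, 23 in each direction moved by at least 2-fold in RPKM plus 1, a scale that understates the folds of low genes.

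Among genes that met the naming rule, the other large decreases were those of Slc15a2 (log2 fold change -1.44, SE 0.06), the ribosomal protein gene Rpl30 (-1.39, SE 0.09), Dipk1a (-1.32, SE 0.10), the Polycomb gene Cbx7 (-1.31, SE 0.05) and Pou6f1 (-1.25, SE 0.06), and the other increases those of Dynlt1b (1.15, SE 0.09) and Prickle1 (1.14, SE 0.06). The pseudogene Rplp0-ps1, which that rule leaves out, rose more (2.61 to 92.2 RPKM). Col1a1 (1.28, SE 0.22), Saa3 (1.13, SE 0.18) and Ppic (1.01, SE 0.15) also rose, but each lost its call without some replicates: Col1a1 without each replicate but Nr4a1 KO replicate 1 (adjusted p = 0.0579 to 0.0765), Saa3 without Nr4a1 WT replicate 2 or 3 or Nr4a1 KO replicate 2 or 3 (0.058 to 0.0878), and Ppic without Nr4a1 WT replicate 1 or 2 or Nr4a1 KO replicate 2 or 3 (0.0632 to 0.0761). Several of these genes lie on chromosome 15 with Nr4a1: Osr2 at 35296098 to 35303305, Rpl30 at 34440505 to 34443640, Dennd3 at 73512560 to 73572242, Apobec3 at 79891659 to 79915906, Cbx7 at 79915807 to 79971119, Prickle1 at 93499114 to 93595891 and Pou6f1 at 100575318 to 100599984. Prickle1 and Pou6f1 lie within 20 Mb of Nr4a1 and the others farther away. Genes within 20 Mb of Nr4a1 passed the threshold more often than others (21 of 178, or 11.8%, against 4.35%, odds ratio 2.94, Fisher's exact test, two-sided p = 4.44e-05), and so did those on the rest of chromosome 15 (34 of 257, or 13.2%, against 4.13% on other chromosomes, odds ratio 3.54, p = 5.81e-09). In the cultured libraries labelled Nr4a1 KO, 127 of 228 genes within 20 Mb passed (55.7% against 39.8%, odds ratio 1.9, Fisher's exact test, two-sided p = 2.18e-06), and 45% on the rest of the chromosome against 39.7% on others (odds ratio 1.24, p = 0.05). That last difference is not particular to the KO label: the rest of the chromosome gave 67.1% against 60.6% in Nr4a1-OV (odds ratio 1.32, Fisher's exact test, p = 0.0181) and 22.2% against 17.4% in Nr4a1RFP+ against Tim-3+ cells (odds ratio 1.36, p = 0.07). In these 2 comparisons the odds ratios for genes within 20 Mb, against other chromosomes, were 1.13 and 1.01 (Fisher's exact test, p = 0.375 and 0.915). Dropping the genes within 20 Mb from the finished test, without a new fit or adjustment, left 480 genes in Ly108+ cells. These still include the 34 on the rest of chromosome 15.

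Of 19 stem-like and naive-memory genes, 1 rose (Ltb, log2 fold change 0.27) and 1 fell, with 3 adjusted over the list alone. Their median was -0.03, their mean 0.00 and the camera direction lower (adjusted p = 0.724). None of 13 inhibitory receptor and exhaustion genes passed (0 adjusted over the list alone, adjusted p = 0.891), Havcr2 averaging 4.94 ± 0.324 RPKM in the libraries labelled Nr4a1 KO and 6.22 ± 0.551 in those labelled Nr4a1 WT. None of 18 cytotoxic effector genes passed (2 adjusted over the list alone, adjusted p = 0.229), with Nkg7 at an adjusted p = 0.0573, although it passed without Nr4a1 KO replicate 1 (0.0419) and with each count-based tool on recovered reads (0.00146 to 0.016). Gzmc was called higher without Nr4a1 KO replicate 1 (adjusted p = 0.048). None passed of 25 activation-induced transcription factor genes (0 adjusted over the list alone, adjusted p = 0.375), of 15 chemokine receptor, homing and residency genes (0 adjusted over the list alone, adjusted p = 0.724) or of 25 cell cycle genes (0 adjusted over the list alone, adjusted p = 0.243). Of the activation-induced transcription factor list, Dusp2 (log2 fold change 0.22) was called higher without Nr4a1 KO replicate 1 (adjusted p = 0.0146) and with each count-based tool on recovered reads (0.00679 to 0.0342), and Batf (0.30) with upper-quartile factors on recovered reads (0.043). Of the chemokine receptor, homing and residency genes, Cxcr4 (log2 fold change 0.26) was called higher and Itga4 (-0.33) lower with replicate numbers as a block (adjusted p = 0.0343 and 0.0476), without Nr4a1 KO replicate 1 (0.0208 and 0.00682) and with each count-based tool on recovered reads (0.00448 to 0.0255 and 0.00629 to 0.0471). Of 24 T cell receptor signalling and costimulation genes, 2 rose, among them Cd3g (0.23), and 3 fell, among them Cblb, which encodes an inhibitory ubiquitin ligase (-0.23; 6 adjusted over the list alone, adjusted p = 0.868). Of 20 type I interferon response genes, 2 rose and 1 fell (3 adjusted over the list alone, adjusted p = 0.327), with Oas1a at 0.60 and Oasl2 falling from 1.60 to 0.306 RPKM. The log2 fold change of Oasl2, -0.99, is drawn towards 0 by the pseudocount of 1 and was -2.38 on recovered reads in edgeR. Of 19 apoptosis genes, 2 rose and 1 fell (7 adjusted over the list alone, adjusted p = 0.0624), with Bax at 0.32 and Bmf at -0.63. None of 9 heat shock and dissociation stress genes passed (1 adjusted over the list alone, adjusted p = 0.979), although Hspe1 was called higher with upper-quartile factors on recovered reads (0.0487). Without Nr4a1 WT replicate 2 or 3 or Nr4a1 KO replicate 2 or 3, none of Ltb, Cd3g, Cblb, Oas1a, Bax and Bmf passed (adjusted p = 0.0546, for Oas1a without Nr4a1 WT replicate 2, to 0.177, for Ltb without Nr4a1 KO replicate 2). Without Nr4a1 WT replicate 1, Ltb (0.0948), Cd3g (0.0867), Cblb (0.064), Oas1a (0.0642) and Bax (0.0867) did not pass. With replicate numbers as a block, Ltb did not pass either (adjusted p = 0.0649).

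In Ly108+ cells, 5 lists were higher in the libraries labelled Nr4a1 KO at the preset correlation, but none passed with an estimated correlation (adjusted p = 0.321 for each). Of 17 glycolysis genes, 3 rose and 0 fell (8 adjusted over the list alone, adjusted p = 0.0308), with Pgk1, which encodes phosphoglycerate kinase, at 0.79. The median log2 fold change of that list was only 0.09. Of 17 oxidative phosphorylation genes, 2 rose and 0 fell (4 adjusted over the list alone, adjusted p = 0.0113), with Cox4i1 at 0.31 and a list median of only 0.08. Of 15 cytokine and chemokine ligand genes, Spp1 and Il10 (0.51) rose and 0 fell (2 adjusted over the list alone, adjusted p = 0.00988). Of 11 myeloid markers, 3 rose and 0 fell (7 adjusted over the list alone, adjusted p = 0.00108): the lysozyme gene Lyz2 rose from 45.7 to 81.0 RPKM (log2 fold change 0.80), Cd14 from 5.37 ± 1.01 to 9.31 ± 0.816 and the complement gene C1qb from 5.71 ± 0.872 to 9.33 ± 1.44. Of 8 tumour and stromal markers, 1 rose, the collagen gene Col1a1 (1.35 ± 0.551 to 4.70 ± 1.40 RPKM), and 0 fell (6 adjusted over the list alone, adjusted p = 0.00988). The cytokine and the tumour and stromal lists did not pass without Nr4a1 KO replicate 1 (adjusted p = 0.0607 each), nor glycolysis without Nr4a1 KO replicate 1 (0.12) or Nr4a1 WT replicate 1 (0.0608). Of the genes, Lyz2 (adjusted p = 0.0726 to 0.125), C1qb (0.0944 to 0.133), Col1a1 (0.0579 to 0.0765), Cox4i1 (0.0894 to 0.156) and Il10 (0.0682 to 0.114) did not pass without any one replicate but Nr4a1 KO replicate 1. On recovered reads Il10 had an adjusted p = 0.05 to 0.119. Cd14 did not pass without Nr4a1 WT replicate 2 or 3 or Nr4a1 KO replicate 2 or 3 (0.0714 to 0.0909). With replicate numbers as a block, neither Cd14 (adjusted p = 0.0529) nor Col1a1 (0.0561) passed.

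Remaining markers in Ly108+ cells gave Ighm, higher in the libraries labelled Nr4a1 KO (log2 fold change 0.46, the 1 member called of 2 B cell markers, 1 adjusted over the list alone, adjusted p = 0.0535 for the list). Fcer1g rose (0.62) as the 1 member called of 2 NK and innate lymphocyte markers (1 adjusted over the list alone, adjusted p = 0.0624). Ikzf2 fell (-0.39) as the 1 member called of 4 CD4 and regulatory T cell markers (1 adjusted over the list alone). The median of that list was 0.03 and its mean -0.05 (adjusted p = 0.661). None of 3 erythroid markers passed (0 adjusted over the list alone, adjusted p = 0.189). Fcer1g did not pass without Nr4a1 WT replicate 1 or 3 or Nr4a1 KO replicate 2 or 3 (adjusted p = 0.0925 to 0.136). Nor did it pass with replicate numbers as a block (0.0596) or with DESeq2 on recovered reads (0.062). Ikzf2 did not pass without Nr4a1 WT replicate 2 or 3 or Nr4a1 KO replicate 2 or 3 (0.0726 to 0.0885).

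The groups of Ly108+ cells did not overlap for 29.4% of genes, against 10% by chance, and the authors called 1040 genes, 434 of them called here with the same sign. The count of 501 was 157, 79 and 78 without Nr4a1 WT replicates 1, 2 and 3, and 1706, 99 and 118 without Nr4a1 KO replicates 1, 2 and 3. Count-based tools on recovered reads called 972 to 991 genes with more decreases than increases: 352 higher and 623 lower with edgeR, 348 and 643 with DESeq2, and 334 and 639 with limma-voom, though 425 and 552 with edgeR and upper-quartile scaling. Of 39 named genes past the threshold other than Nr4a1, 15 passed without each replicate in turn: Apobec3, Cbx7, Ctse, Dennd3, Dipk1a, Dynlt1b, Ighm, Oasl2, Osr2, Pgk1, Pou6f1, Prickle1, Rpl30, Slc15a2 and Spp1.

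**Figure D3:**
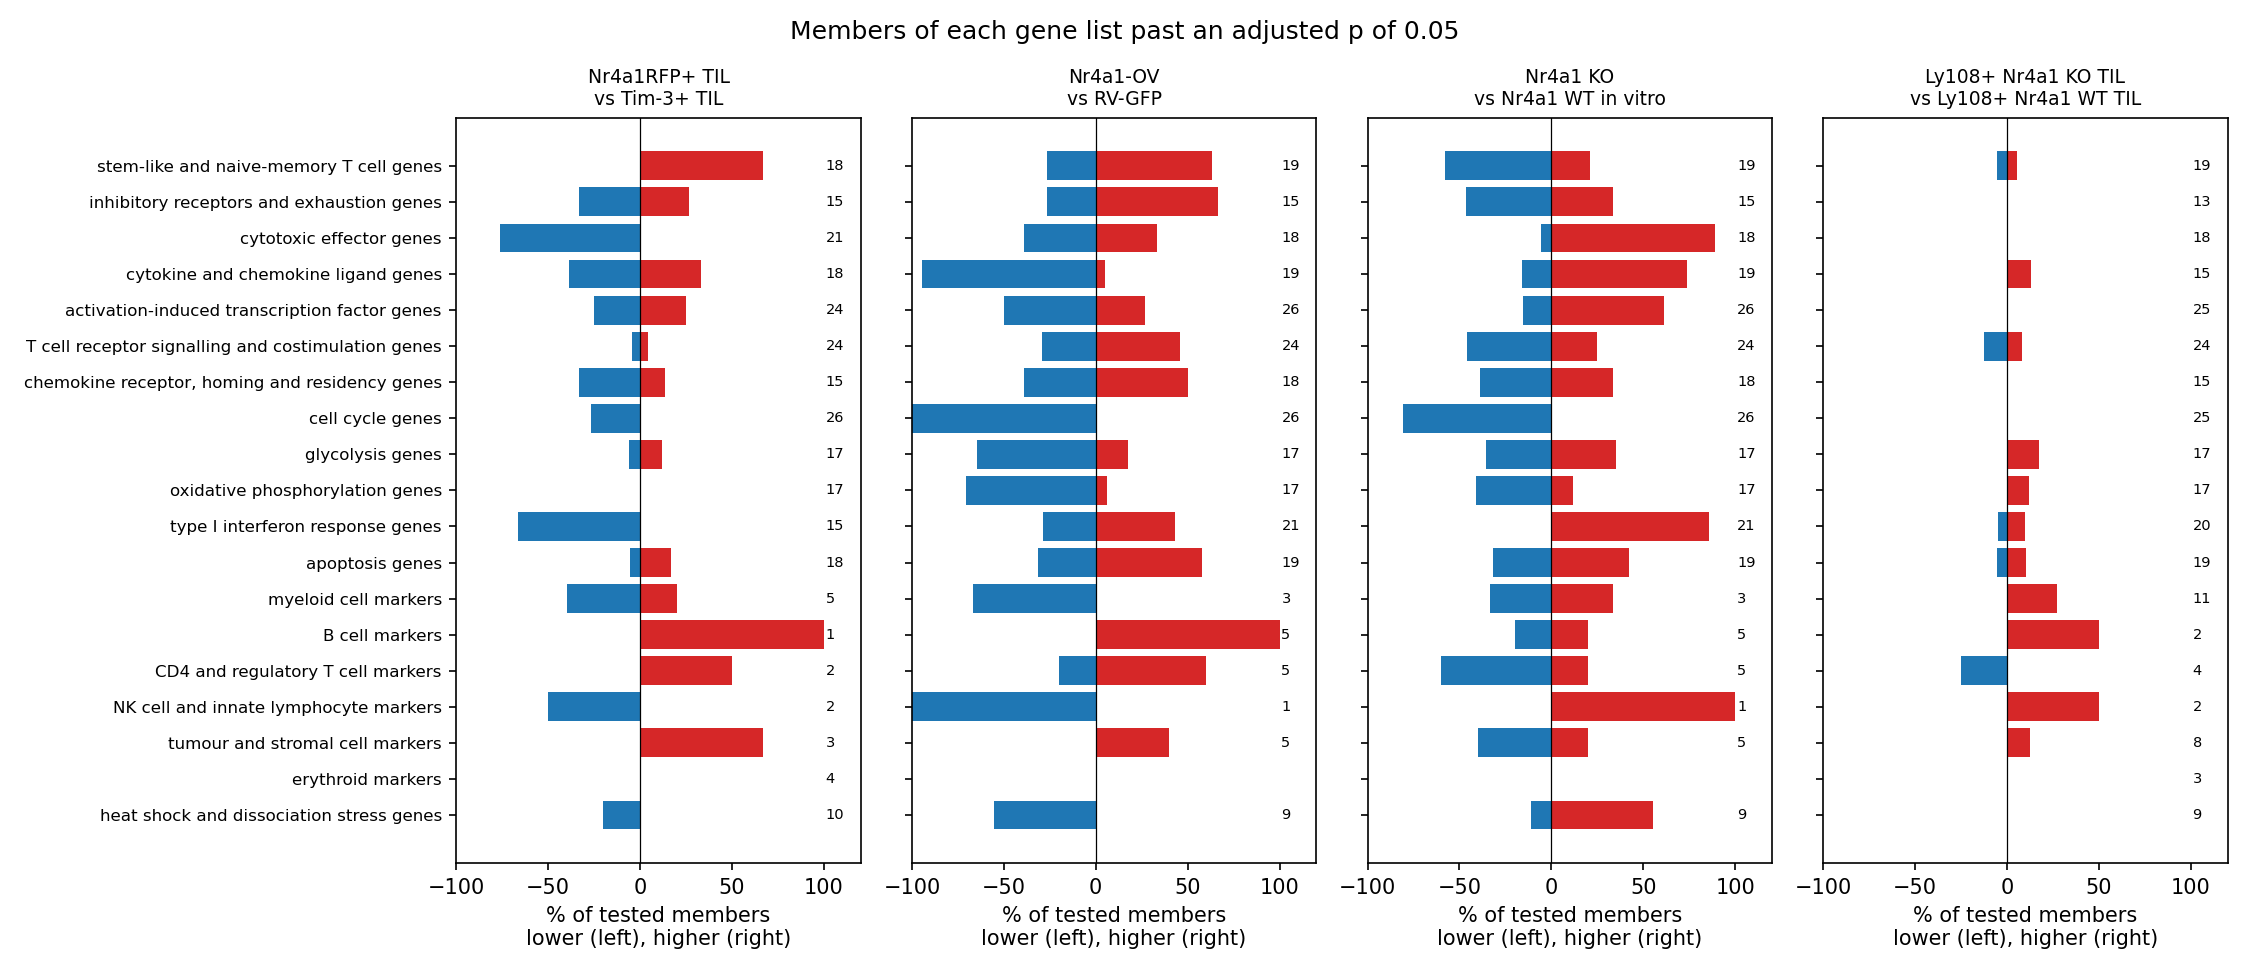
Share of the tested members of each gene list (%, horizontal axis) past an adjusted p of 0.05 as lower (blue bars, left) or higher (red bars, right) in each of the 4 comparisons (panels), with the number of members tested beside the bars. Of 19 cytokine and chemokine ligand genes, 18 were lower in Nr4a1-OV cells and 14 higher in cultured cells labelled Nr4a1 KO, while few members of any list passed in Ly108+ cells.

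Sets of up to 200 genes from the cultured cells were then tested in the tumour cells, to ask whether the genes that changed there part the sorted populations. Genes higher in Nr4a1-OV cells were higher in Nr4a1RFP+ than in Tim-3+ cells: 70 rose and 11 fell of 171 tested (camera adjusted p = 1.44e-08, and 0.299 with an estimated correlation). Genes higher in the cultured libraries labelled Nr4a1 KO were lower in Nr4a1RFP+ cells, where 30 rose and 59 fell of 160 (adjusted p = 0.000736, and 0.118 with an estimated correlation). The genes lower in Nr4a1-OV cells (22 higher and 28 lower of 180, adjusted p = 0.987) and lower in the libraries labelled Nr4a1 KO (46 higher and 22 lower of 157, adjusted p = 0.0685) did not pass. In Ly108+ cells, genes higher in Nr4a1-OV were lower in the libraries labelled Nr4a1 KO (1 rose and 16 fell of 176, adjusted p = 1.55e-06, and 0.295 with an estimated correlation). Genes higher in Tim-3+ cells were higher there (5 rose and 3 fell of 146, adjusted p = 0.0268, and 0.227 with an estimated correlation). Genes lower in Nr4a1-OV (adjusted p = 0.401), higher or lower in the cultured libraries labelled Nr4a1 KO (0.779 and 0.792) and higher in Nr4a1RFP+ cells (0.737) did not pass in Ly108+ cells.

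The effects labelled Nr4a1 KO in Ly108+ and in cultured cells shared more genes than for independent calls, but often with opposite signs. Of 10719 genes tested in both, 262 passed the threshold in both, 56.1% of the 467 called in Ly108+ cells (212 for independent calls). They comprised 73 higher in both (42.4 for independent calls, Fisher's exact test, two-sided p = 8.67e-07), 73 lower in both (64.5, p = 0.215), 64 lower in Ly108+ and higher in culture (50.6, p = 0.0385) and 52 with the reverse signs (54, p = 0.811). As genes are not independent replicates, these exact tests describe the overlap only. Nr4a1, Spp1, Prickle1 and Dennd3 were higher and Apobec3 and Slc15a2 lower in both, while Oasl2 was higher in culture and lower in Ly108+ cells. Nr4a1, Prickle1, Dennd3 and Apobec3 lie on chromosome 15, where shared signs were more frequent than on other chromosomes, as given below. Across genes, the fold changes had a Pearson r of -0.0723 and a Spearman rho of 0.0125. The count of 262 was 96, 52 and 51 without Ly108+ Nr4a1 WT replicates 1, 2 and 3, and 813, 67 and 73 without Ly108+ Nr4a1 KO replicates 1, 2 and 3.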

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

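The interaction, the set of oppositely changed genes, the window around Nr4a1 and the tests of location, pseudogenes and exchanged labels were chosen only after these results had been seen. The difference between Nr4a1 KO and Nr4a1 WT was compared between Ly108+ cells and cultured cells as an interaction in edgeR, and it differed for 3264 genes. Reads were recovered from RPKM for the Ly108+ libraries and deposited as counts for the cultured ones, and library preparation may have differed too. The design cannot tell these differences apart from that between the cells. The smallest adjusted p was that of Rplp0-ps1, a processed pseudogene of a ribosomal protein gene, whose log2 fold change was 10.1 higher in Ly108+ than in cultured cells. Oasl2 differed by -7.56, being lower in the Ly108+ libraries labelled Nr4a1 KO and higher in the cultured ones. Nr4a1 differed by 0.908, a larger increase in Ly108+ cells.

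A set of 12 genes had large and opposite differences in the 2 settings. Other genes moved as far in the same direction in both. Dennd3 had a log2 fold change of 2.018 in Ly108+ and 3.409 in cultured cells, and Apobec3 of -2.451 and -2.964. Rplp0-ps1 averaged 92.2 RPKM in Ly108+ Nr4a1 KO and 2.61 RPKM in Ly108+ Nr4a1 WT libraries, but 69.9 CPM in cultured Nr4a1 WT, 2.18 in cultured Nr4a1 KO, 2.1 in Nr4a1-OV and 2.36 in RV-GFP libraries. An exchange of labels in 1 setting would turn genes near Nr4a1 to opposite signs only if both settings shared a linked difference. Of 13 such genes, Nr4a1 included, 1 went opposite ways (7.69%, 95% interval up to 36%). That count is the complement of the same-way count given below. It argues against an exchange only under that assumption. Of the 12 genes, 10 were pseudogenes or unnamed predicted genes (83.3%, 51.6% to 97.9%), against 17% of all genes in the interaction (Fisher's exact test, two-sided p = 9.28e-07). Reads shared between related sequences could give such a share, but the share does not say why groups differed. Gm5948, a processed pseudogene, averaged 51.5 RPKM in Ly108+ Nr4a1 KO and 0.0767 in Ly108+ Nr4a1 WT libraries. In culture it averaged 34.7 CPM in Nr4a1 WT, 0.057 in Nr4a1 KO and 0 in Nr4a1-OV and RV-GFP libraries. Like Rplp0-ps1 and Gm5948, Gm9625, Gm8730, Gm8199, Gm6278, Gm42031 and Gm5340 were far higher in cultured Nr4a1 WT than in every other cultured group. For these genes the cultured Nr4a1 WT libraries, not those labelled Nr4a1 KO, stood apart. Oasl2, A630023P12Rik, Mgll and Gm10382 were not highest in cultured Nr4a1 WT. A strain or donor variant elsewhere in the genome stays open, and would bear on the KO differences, Oasl2 included: 0 of the 12 lay within 20 Mb of Nr4a1, but only 1.63% of all genes did, so their location decides nothing.

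Genes near Nr4a1 that passed the threshold in both KO comparisons changed the same way for 12 of 13 (92.3%, 95% interval 64% to 99.8%), against 133 of 248 elsewhere (Fisher's exact test, two-sided p = 0.00761), and without Nr4a1 itself for 11 of 12 (p = 0.014). On the rest of chromosome 15 it was 20 of 23, against 113 of 225 on other chromosomes (exact test, p = 0.000711), so the pattern is not confined to the window. Celsr1 was the exception within the window. A strain variant carried with the targeted allele would give this pattern. A general effect of the genotype shared by both settings would also give same signs, but not on chromosome 15 alone. The 113 of 225 on other chromosomes do not show such an excess of same signs. Differences of opposite sign, as in the 12 genes above, could offset a general effect there, so this share does not exclude one. Of genes near Nr4a1 called in Ly108+ cells and in Nr4a1-OV, 4 of 10 went opposite ways (40%, 12.2% to 73.8%), so an effect of Nr4a1 on its neighbours cannot be told apart from its absence.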

How the results depend on the processing

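The tests on recovered reads, median-ratio scaling, removal of genes within 20 Mb of Nr4a1 and the overlap without single replicates were chosen only after the data had been seen. Requiring an absolute log2 fold change of at least 1 left 493 genes (Nr4a1RFP+ against Tim-3+), 2387 (Nr4a1-OV), 998 (cultured Nr4a1 KO) and 46 (Ly108+). For Ly108+ cells, recovered reads gave 975 genes with edgeR, 972 with RLE and 977 with upper-quartile scaling, 991 with DESeq2 and 973 with limma-voom, against 501. Leaving out a replicate gave 763 (Nr4a1RFP+ replicate 2) to 3359 (Tim-3+ replicate 2) genes in the first comparison and 78 (Nr4a1 WT replicate 3) to 1706 (Nr4a1 KO replicate 1) in Ly108+ cells. The cause of these shifts was not tested. Nr4a1 in the cultured libraries labelled Nr4a1 KO had a log2 fold change of 0.0966 without Nr4a1 WT replicate 1 and 0.313 without Nr4a1 WT replicate 2. Hba-a1 lay at 1.17 without Nr4a1RFP+ replicate 1 and -2.48 without replicate 2, and Hba-a2 at 1.11 and -2.93. With an estimated correlation 0, 0, 2 and 0 lists passed in the 4 comparisons, and with fry 8, 15, 16 and 8. For Ly108+ cells, 2 lists passed without Nr4a1 KO replicate 1 and 8 without Nr4a1 WT replicate 2.

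For the gene sets in Nr4a1RFP+ against Tim-3+ cells, an estimated correlation gave an adjusted p = 0.299 for genes higher in Nr4a1-OV and 0.118 for genes higher in cultured Nr4a1 KO. Genes lower in Nr4a1-OV turned direction with the top 100 (0.307) or 500 (0.705), and genes lower in cultured Nr4a1 KO passed with the top 100 (0.00608). In Ly108+ cells, genes higher in Nr4a1-OV gave 0.295 and genes higher in Tim-3+ cells 0.227 with an estimated correlation, the latter 0.0615 with the top 500, which passed with an estimated correlation (0.0431). Genes lower in cultured Nr4a1 KO (top 500, 0.859) and higher in Nr4a1RFP+ cells (top 100, 0.629) turned direction. The overlap of both KO comparisons was 507 genes with edgeR and 457 with DESeq2 on recovered reads, and 51 (without Ly108+ Nr4a1 WT replicate 3) to 813 (without Ly108+ Nr4a1 KO replicate 1) when a replicate was left out. Treating replicate numbers as a block gave 2143, 9803, 5871 and 485 genes. In culture the block was fitted to only the 4 libraries compared, which gave 9051 and 5770 genes without it. In Ly108+ cells the block kept 340 of the 501 calls and ended those of Cd14 (adjusted p = 0.0529), Col1a1 (0.0561), Fcer1g (0.0596) and Ltb (0.0649). Ltb also failed with no low-value filter (0.0587), a pseudocount of 0.1 (0.0502) and median-ratio scaling (0.0522). The planned tests of deposited tumour counts, the interaction on deposited counts and a pseudocount change for cultured cells were not run.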

Other observations

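The count of markers and the removal of single libraries for the tumour and stromal markers were chosen only after the result had been seen. In Ly108+ libraries labelled Nr4a1 KO, 16 of 19 myeloid and stromal markers lay above those labelled Nr4a1 WT (84.2%), a count that restates the higher lists and does not test whether the RNA came from other cells. Lyz2 averaged 81.0 against 45.7 RPKM, and Col1a1 4.70 against 1.35 RPKM. Without Ly108+ Nr4a1 KO replicate 1, the median log2 fold change of the myeloid markers kept 106% of its size and that of the tumour and stromal markers 79.5%, which argues against that library alone as the source of the medians, although the latter list no longer passed (adjusted p = 0.0607). A sort of OT-I cells for Ly108 should remove such cells, and S100a8 (1.26 against 1.84 RPKM) and S100a9 (2.07 against 2.77 RPKM) lay lower. Whether other cells or the T cells themselves made these transcripts stays open.

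Splits of the 6 Ly108+ libraries into groups of 3 gave 10 arrangements, of which 1, the labelled one, reached 501 genes, and the highest of the others called 0. With 10 splits, a share under 0.05 cannot be reached.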
